A study of Homo sapiens with 19 samples.

How the data were processed

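Regulatory T cells (Tregs) and CD4 effector T cells (Teffs) were sorted from collagenase-digested human skin, either healthy or from psoriatic lesions, and their RNA was sequenced. Per the labels' protocols, live single cells positive for CD45, CD3 and CD4 and negative for CD8 were split into Tregs (CD25 and CD27 positive) and Teffs (CD25 and CD27 negative). RNA was extracted on spin columns, cDNA was made from 220 pg of RNA with the SMARTer Ultra Low kit, and 50 bp paired-end reads without strand information were sequenced. The 19 libraries fall into 4 groups: 5 of healthy Treg, 5 of psoriasis Treg, 5 of healthy Teff and 4 of psoriasis Teff. The labels number the libraries within each group, and psoriasis Teff has no library numbered 3. Nothing in the labels states that each number is a separate donor, so p-values measure the spread between these samples.

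The authors' deposited values are raw read counts per gene for each library, with no normalization. Per the submitters' processing notes, the tools were TopHat2 2.0.12, SAMtools and HTSeq 0.6.1p1, with the genome build hg19 (GRCh37), and no role was stated for any of them. The gene annotation release and the strand setting of the counter are not given in the sources used here. Because the reads carry no strand, the reads of a gene and of an overlapping or antisense partner cannot be told apart, and genes with near-identical copies may share or lose reads. The table holds 63677 gene identifiers and 5 lines in which the counter summed reads it assigned to no gene. These 5 lines were left out of library sizes and tests. Of all entries in a library, 4.7% to 18.94% had no gene feature, 3.02% to 4.3% were ambiguous and 35.49% to 45.63% were not uniquely aligned.

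Gene symbols came from a table of Ensembl identifiers for 52181 identifiers and from GENCODE release 29, a GRCh38 annotation used for names alone, for 345 more. No GRCh37 annotation was used, so no coordinates are given. Identifiers without a symbol took 0.866% to 1.662% of the gene counts and stayed in the tests without being named. A set of 75 identifiers that mark sex was left out throughout. No pair of libraries matched within sampling noise (lowest chi-square per gene between libraries 68.2), and each was counted as 1 sample.

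The counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors (0.681 to 1.252), the default expression filter by group, robust quasi-likelihood fits over all 19 libraries with 1 mean per group, and a two-sided F test with Benjamini-Hochberg adjustment over the 18968 genes that passed the filter. A gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 0.90. Log2 fold changes are given with a standard error (SE) that was derived from the F statistic, and levels as CPM (counts scaled to a common library total) with the SD between libraries. In all, 5 comparisons were tested: psoriasis against healthy skin in each population, Treg against Teff in each kind of skin, and the difference between the psoriasis effects of the populations. Gene lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Adjusted p-values of lists are over the 36 lists of a comparison that had at least 3 tested members. The 38 lists hold T cell programmes, metabolic pathways and markers of other skin cell types, and 621 of their 623 entries matched a gene in the table. A camera call compares a list with all other genes, while fry asks whether the list's genes move, on balance, in 1 direction.

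The comparisons, tests, lists and rule for named genes were chosen before the data were examined. In each comparison between groups, the rule took the 8 higher and the 8 lower genes with the smallest p among called genes with at least 1 CPM in the higher group and a proper gene name. Where fewer than 5 passed in a direction, all that passed were named together with up to 5 that did not. The difference between the effects took 5 genes per direction, each described list 2 to 4 members with the smallest p, and FOXP3, IL2RA, CD27, CTLA4, IKZF2, ARG2, LAYN, IL17A, IL17F, IL22, IL26, IFNG, IL10, IL23R, CCR6 and TNFRSF4 were followed throughout. Antigen receptor segments and genes that differ by germline deletion or haplotype between people were tested and not named, and 1 list member that the rule takes is not reported here.

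Alternatives planned at the same time were DESeq2 size factors or upper-quartile factors within edgeR, no filter, a filter of at least 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with sample quality weights, a fit of the 2 compared groups alone, the replicate number as a block, and the omission of each library in turn. After the data were examined, a fit without the 4 libraries with fewer than 20000 detected genes (healthy Treg 5, psoriasis Treg 2, healthy Teff 4 and psoriasis Teff 1), upper-quartile factors for the list tests, and the share of reads outside genes as a quality measure were added.

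The procedure was tested on counts simulated for the real genes, library sizes and groups with 200 changed genes. The changed genes were taken from the more abundant ones, so the recovery does not cover genes at low counts. Genes were drawn independently with edgeR's own dispersions, which may favour edgeR over DESeq2. At true folds of 4, 16 and 64, edgeR recovered 22.4%, 65.7% and 83.3% of changed genes for psoriasis against healthy Treg (18163 genes tested, 1 false call), and 26.9%, 58.2% and 74.2% for Teff (18157 genes, 6 false calls). It recovered 25.4%, 73.1% and 89.4% for Treg against Teff in healthy skin (18184 genes, 6 false calls), 23.9%, 64.2% and 83.3% in psoriasis (18008 genes, 6 false calls), and 6.0%, 40.3% and 69.7% for the difference of effects (18178 genes, 3 false calls). DESeq2 made 64, 87, 89, 54 and 77 false calls in the same order.

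Library measures (gene counts, genes detected, share of the 50 most abundant genes, mitochondrial share and summed CPM of each list of another cell type) were compared by exact two-sided permutation tests of means, adjusted over the measures of a comparison, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The sums cover only genes that passed the expression filter, which were fewer than 3 for mast cell and for red cell markers. Plots were drawn with matplotlib 3.10.9. Where all libraries of a group had 0 counts, the fold is a lower bound against 3 counts over the whole group, which equal 0.0407 CPM in healthy Treg, 0.0357 in psoriasis Treg, 0.0402 in healthy Teff and 0.0438 in psoriasis Teff. Where a group held 1 to 3 counts, the ratio is given with its 0.95 counting interval. The reads carry no molecular identifiers, so these floors and intervals cover counting error alone.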

Results

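The data comprised RNA sequencing libraries of Tregs, the FOXP3-dependent suppressive CD4 T cells, and of CD4 Teffs from healthy human skin and psoriatic lesions. There were 5 healthy Treg, 5 psoriasis Treg, 5 healthy Teff and 4 psoriasis Teff libraries. Counts assigned to genes ranged from 13946759 to 18525504 per library, with 18677 to 23964 genes detected. The 50 most abundant genes took 17.17% to 27.13% of the counts and mitochondrially encoded genes 3.056% to 8.033%. On the leading principal component, which held 18.6% of the variance, Treg libraries lay between -107.89 and 3.83 and Teff libraries between 19.33 and 93.31.

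Which genes separate Tregs from Teffs was asked first in healthy skin, where edgeR's quasi-likelihood test called 91 genes higher and 105 lower in Treg (n = 5 and 5). IL2RA (ENSG00000134460), which encodes the sort marker CD25, was at 1320 ± 409 CPM in Treg and 47.8 ± 23.1 CPM in Teff (SD), a log2 fold change of 4.79 ± 0.56 (SE, adjusted p = 0.000249). FOXP3 (ENSG00000049768), the transcription factor that defines Tregs, rose by 6.05 ± 1.28 (180 ± 128 against 2.68 ± 3.46 CPM, adjusted p = 0.0258). The Helios gene IKZF2 rose by 3.85 ± 0.71 (adjusted p = 0.0124). The second sort marker CD27 rose by 2.89 ± 0.58 (adjusted p = 0.0186) and the hyaluronan receptor gene LAYN by 5.60 ± 1.10 (adjusted p = 0.0181). The inhibitory receptor gene TIGIT (ENSG00000181847) rose by 2.76 ± 0.35, to 2850 ± 339 CPM (adjusted p = 0.000663). CTLA4, another inhibitory receptor gene, did not pass (1.87 ± 0.63, adjusted p = 0.199). The plot of single genes per library shows these levels.

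**Figure D1:**
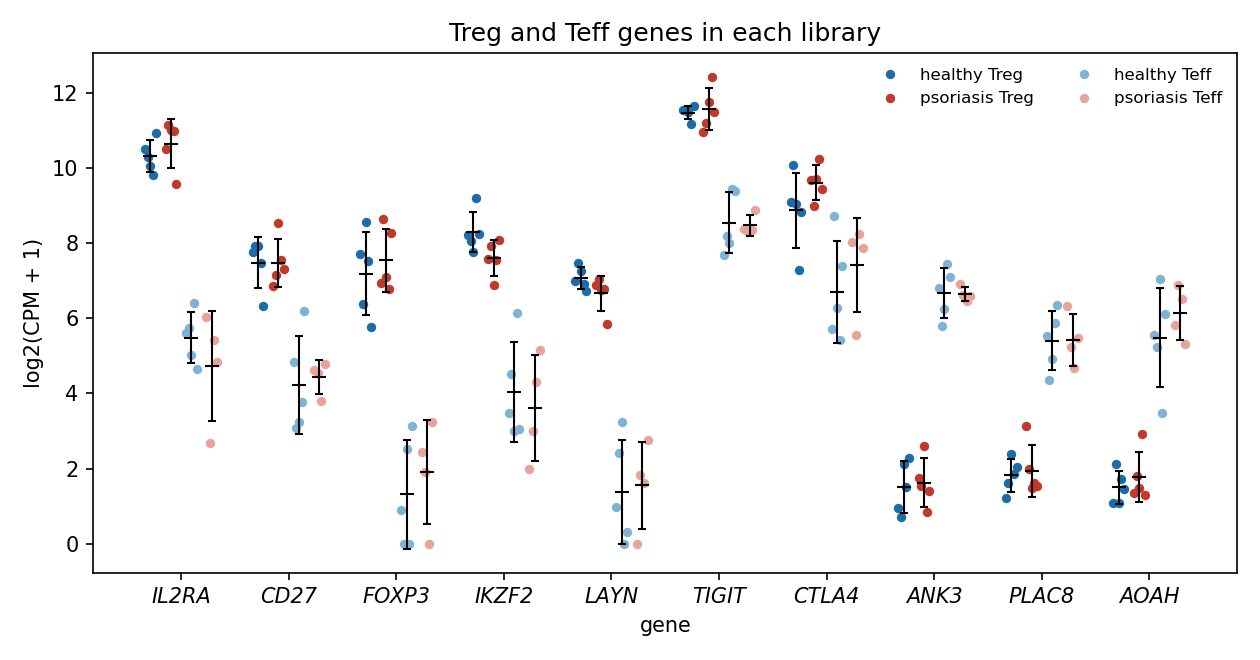
Levels of 10 genes, as log2(CPM + 1), in each of the 19 libraries, by group; points are libraries, bars are group means and error bars the SD. IL2RA and TIGIT lay higher, and ANK3, PLAC8 and AOAH lower, in Treg than in Teff libraries of both healthy and psoriatic skin.

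Of the genes higher in healthy Treg with the smallest p, ADAT2 (ENSG00000189007), part of the adenosine deaminase that edits tRNA, rose by 4.46 ± 0.48 on the log2 scale (347 ± 171 against 15.7 ± 6.32 CPM, adjusted p = 0.000178). The noncoding transcript MIR4435-2HG rose by 3.46 ± 0.39, the inflammatory caspase gene CASP1 by 2.41 ± 0.28 (617 ± 207 against 116 ± 42.8 CPM) and its decoy CARD16 by 3.09 ± 0.35, each with an adjusted p = 0.000249. CASP1 and CARD16 are near-identical in part, so their split of reads is uncertain. ZNRF2, a ubiquitin ligase gene, rose by 1.96 ± 0.23 and the noncoding LINC02099 by 5.27 ± 0.65. On the Teff side, ANK3 (ENSG00000151150), which encodes the membrane anchor ankyrin G, was at 2.12 ± 1.42 CPM in Treg and 110 ± 47.5 CPM in Teff (-5.69 ± 0.59, adjusted p = 0.000178). NR3C1 (ENSG00000113580), the glucocorticoid receptor gene, was lower by a log2 fold change of -2.36 ± 0.30 (adjusted p = 0.000646). PLAC8 (-4.11 ± 0.56), the lipopolysaccharide hydrolase gene AOAH (-4.90 ± 0.68), the small GTPase gene GIMAP7 (-2.86 ± 0.41) and the annexin gene ANXA1 (-3.85 ± 0.55, 131 ± 77.9 against 1890 ± 383 CPM) shared an adjusted p = 0.00127. TC2N fell by 3.97 ± 0.57 (adjusted p = 0.00148). The tetraspanin gene TSPAN2 had 1 count in all Treg libraries against 1690 in Teff, a ratio of 1670 (counting interval 299 to 65900, adjusted p = 0.00127).

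The 30 tested genes of the Treg identity list, from which the sort markers were left out, rose as a group in healthy Treg (median log2 fold change 1.89, camera adjusted p = 1.14e-21, and adjusted p = 0.000227 with an estimated correlation). Of these, 27 had positive fold changes, 7 were called higher and 17 were higher when adjusted over the list alone. Besides TIGIT and IKZF2, the protease gene CTSC rose by 1.80 ± 0.30 (adjusted p = 0.0052) and the chemokine receptor gene CCR8 by 3.46 ± 0.65 (740 ± 303 against 67.5 ± 40.4 CPM, adjusted p = 0.0134). Genes of recirculation and central memory fell as a group (median -1.21, adjusted p = 1.24e-05, and adjusted p = 0.0252 with an estimated correlation). Among its 12 tested genes 2 were called lower, TCF7, a transcription factor of memory cells (-3.67 ± 0.70, adjusted p = 0.0151), and S1PR1, the receptor for exit from tissue (-3.29 ± 0.65, adjusted p = 0.0186). Adjusted over the list alone, 5 were lower and 1 higher. S1PR1 was no longer called without healthy Treg 2 (adjusted p = 0.0513, with 6.61e-06 to 0.0513 over its alternatives).

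The TGF-beta pathway list was lower in healthy Treg by camera (median -0.20 over 18 genes, adjusted p = 0.0044, and adjusted p = 0.034 with an estimated correlation), with 1 gene called lower and 6 lower when adjusted over the list alone. The coreceptor gene TGFBR3 (betaglycan) fell by 2.74 ± 0.44 (50.3 ± 21.7 against 337 ± 187 CPM, adjusted p = 0.00382). The signal transducer gene SMAD3 was at -1.37 ± 0.37 without passing (adjusted p = 0.0953). Interferon-stimulated genes were higher by camera (median 0.77, adjusted p = 0.000971), a call lost at an adjusted p = 0.121 with an estimated correlation. Of its 29 genes, 4 were called higher and 1 lower, against 6 and 1 when adjusted over the list alone. The antiviral gene OAS1 rose by 3.18 ± 0.46 (268 ± 117 against 29.6 ± 7.77 CPM, adjusted p = 0.0015). The guanylate binding protein genes GBP5 and GBP2 rose by 3.04 ± 0.50 and 1.88 ± 0.33 (adjusted p = 0.00457 and 0.00753).

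The list of CD8 T cell markers fell in healthy Treg (5 tested genes, 2 called lower and 3 lower when adjusted over the list alone; adjusted p = 0.000488, and adjusted p = 0.0201 with an estimated correlation), with a median of -8.78 that becomes -7.92 with genes at 0 set to their bound. EOMES, a transcription factor of cytotoxic cells, had 1 count in Treg and 692 in Teff (ratio 683, counting interval 122 to 27000, adjusted p = 0.0246). The chemokine gene XCL1 was at least 282-fold lower (adjusted p = 0.0348). The EOMES call was lost without any 1 of the 5 healthy Treg libraries or healthy Teff 1 (adjusted p from 0.0535 to 0.0853). The XCL1 call was lost without any single library other than healthy Teff 5 (adjusted p from 0.051 to 0.0729). Of the 8 genes listed as CD8 markers, 7 are on other lists too, so a lower list or sum does not by itself mark CD8 T cells. The summed level of the CD8 list was 4.32 ± 2.19 CPM in Treg and 45.1 ± 22.5 CPM in Teff (exact permutation p = 0.00794, adjusted p = 0.127), and that of B and plasma cell markers 121 ± 52.1 and 40.9 ± 14.5 CPM (exact permutation p = 0.0238, adjusted p = 0.19). Keratinocyte markers were lower in Treg by camera (median -1.77, 13 of 14 genes negative, adjusted p = 0.00137, but adjusted p = 0.372 with an estimated correlation), a call lost without healthy Teff 2 (0.103). Their sums were 88.7 ± 96.2 and 284 ± 300 CPM (exact permutation p = 0.167, adjusted p = 0.533). Immediate early and dissociation stress genes were lower by camera as well (median -0.64, adjusted p = 0.000315, but adjusted p = 0.203 with an estimated correlation). Cholesterol synthesis genes (median -0.92, adjusted p = 0.000971 and, with an estimated correlation, adjusted p = 0.0255) and T cell receptor activation genes (median -1.06, adjusted p = 0.00131 and, with an estimated correlation, adjusted p = 0.0255) were the other lists to hold. In the former no gene was called (1 lower when adjusted over the list alone), with FDFT1 at -1.15 ± 0.38. In the latter 2 genes were lower and 1 higher (4 and 1 when adjusted over the list alone). XCL1 is on this list too. The growth factor gene IL2 was at least 157-fold lower (adjusted p = 0.0454), and the transferrin receptor gene TFRC rose by 1.13 ± 0.26 (adjusted p = 0.0469). The IL2 call was lost without any single library other than healthy Teff 4 (adjusted p up to 0.0898). The TFRC call was lost without any single library other than healthy Treg 2 or 3 (adjusted p up to 0.125).

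The cytokine genes followed throughout did not pass in healthy skin. IFNG was at 0.78 ± 1.04 CPM in Treg and 22.3 ± 17.3 CPM in Teff (-4.81 ± 1.32, adjusted p = 0.119). IL17A was at least 371-fold lower in Treg (0 against 15.1 ± 23.1 CPM, adjusted p = 0.294). IL17F (-4.89 ± 2.88), IL22 (-3.17 ± 2.18), IL26 (-3.38 ± 1.83) and IL10 (-1.65 ± 1.06) lay below 0 within wide errors. The arginase gene ARG2 was at 61.1 ± 33.3 CPM in Treg and 3.09 ± 3.23 CPM in Teff (4.30 ± 1.18, adjusted p = 0.102). IL23R (-0.58 ± 0.95), CCR6 (0.93 ± 0.55) and TNFRSF4 (0.87 ± 0.72) differed by less than 2 SE.

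The number called in healthy skin was 95 without healthy Treg 1, 123 without healthy Treg 5, 112 without healthy Teff 1, 129 without healthy Teff 3 and 122 without the 4 libraries with the fewest genes. FOXP3 was no longer called without healthy Treg 1 (adjusted p = 0.0562), healthy Treg 3 (0.0518), healthy Teff 1 (0.0761) or healthy Teff 3 (0.0585). CD27 was lost without healthy Teff 1 (0.0525) or 4 (0.055) and LAYN without healthy Teff 1 (0.0544). Over all alternatives the adjusted p ran from 7.35e-06 to 0.0761 for FOXP3, from 1.98e-05 to 0.0691 for CD27 and from 3.66e-07 to 0.0544 for LAYN. The recirculation, TGF-beta and cholesterol synthesis lists were at an adjusted p = 0.0511, 0.0748 and 0.0979 with an estimated correlation when the 4 libraries with the fewest genes were left out.

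In psoriatic skin, Tregs differed from Teffs in 116 genes, 61 higher and 55 lower in Treg (edgeR, n = 5 and 4). IL2RA rose by 5.62 ± 0.64 (1710 ± 614 against 34.7 ± 24.7 CPM, adjusted p = 0.000428) and CARD16 by 3.69 ± 0.40 (adjusted p = 0.000399). CASP1 and TIGIT rose by 2.47 ± 0.30 and 3.17 ± 0.39 (both adjusted p = 0.000931). CTSC, the gene of the granule protease activator cathepsin C, rose by 2.63 ± 0.34 (735 ± 248 against 119 ± 47.5 CPM) and the glutaredoxin gene GLRX by 2.07 ± 0.27 (477 ± 126 against 113 ± 22.3 CPM), both at an adjusted p = 0.00116. MIR4435-2HG (3.18 ± 0.42) and ZNRF2 (1.82 ± 0.25) were again higher. FOXP3 was at 213 ± 129 CPM in Treg and 3.92 ± 3.54 CPM in Teff without passing (5.77 ± 1.39, adjusted p = 0.0738). LAYN did not pass either (104 ± 28 against 2.6 ± 2.41 CPM, 5.31 ± 1.20, adjusted p = 0.051).

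ANK3 was the lower gene with the smallest p (2.36 ± 1.62 against 99.7 ± 13.5 CPM, -5.40 ± 0.59, adjusted p = 0.000399). AOAH (-4.77 ± 0.68, adjusted p = 0.00212), PLAC8 (-3.80 ± 0.57, adjusted p = 0.00288) and NR3C1 (188 ± 50 against 724 ± 196 CPM, -1.95 ± 0.31, adjusted p = 0.00425) were lower in Treg, as in healthy skin. The phosphatase gene PTPN13 (ENSG00000163629) had 3 counts in all Treg libraries and 8099 in Teff (ratio 3320, counting interval 1130 to 16100, adjusted p = 0.00173). TSPAN2 had 1 and 813 (ratio 998, counting interval 179 to 39500, adjusted p = 0.00348). The calcium channel gene CACNA1I was at least 641-fold lower (0 against 22.9 ± 16.5 CPM, adjusted p = 0.00425). The RNA binding protein gene RBMS1 fell by 2.97 ± 0.48 (adjusted p = 0.00525). Without the 4 libraries with the fewest genes the adjusted p of CACNA1I was 0.0749 and that of RBMS1 0.0645, the highest of their alternatives. IFNG, the type 1 effector cytokine, had 0 counts in psoriasis Treg and 22 ± 22.5 CPM in Teff, at least 616-fold lower (adjusted p = 0.013). In a fit of the 2 groups alone IFNG was not called (adjusted p = 0.051, with 1.88e-10 to 0.2 over its alternatives).

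The other cytokine genes did not pass. IL17A (adjusted p = 0.335) and IL17F (adjusted p = 0.325) were at least 387-fold and at least 457-fold lower in psoriasis Treg, where both had 0 counts. IL22 had 1 count against 314 (ratio 386, counting interval 68.7 to 15300, adjusted p = 0.331). In psoriasis Teff, IL17A, IL17F and IL22 were each detected in 1 library alone (55.3, 65.3 and 18.1 CPM), so these folds rest on it. IL26 (-1.66 ± 1.78), IL10 (-0.97 ± 1.09), IL23R (-0.16, adjusted p = 0.986), CCR6 (0.10 ± 0.58), ARG2 (1.48 ± 1.13), CTLA4 (1.95 ± 0.68, adjusted p = 0.259) and the costimulatory receptor gene TNFRSF4 (2.72 ± 0.84, adjusted p = 0.177) did not pass either.

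The Treg identity list was higher as a group in psoriasis as well (median 2.67, 27 of 30 genes positive, camera adjusted p = 1.72e-33, and adjusted p = 2.79e-06 with an estimated correlation). In it 7 genes were called and 22 were higher when adjusted over the list alone. Besides TIGIT and CTSC, CCR8 rose by 5.35 ± 0.79 (325 ± 117 against 7.95 ± 5.69 CPM, adjusted p = 0.00271). The MHC class II list rose (median 1.60, 9 of 10 genes positive, adjusted p = 8.38e-11, and adjusted p = 0.0102 with an estimated correlation). No gene was called and 6 were higher when adjusted over the list alone. Its invariant chain gene CD74 was at 1710 ± 620 CPM in Treg and 470 ± 320 CPM in Teff (1.86 ± 0.42, adjusted p = 0.0512). HLA-DPA1 was at 1.49 ± 0.38 (adjusted p = 0.0904). Genes of recirculation fell as a group (median -1.22, adjusted p = 1.16e-05, and adjusted p = 0.0198 with an estimated correlation). S1PR1 was at -2.71 ± 0.65 and TCF7 at -2.45 ± 0.69, with none called and 5 lower when adjusted over the list alone. The TGF-beta list was again lower (median -0.22, adjusted p = 0.000282, and adjusted p = 0.0102 with an estimated correlation). Of its 18 genes 2 were called and 4 were lower when adjusted over the list alone. The called genes were TGFBR3 (-2.33 ± 0.44, adjusted p = 0.0175) and SKIL, a repressor of the pathway (-3.05 ± 0.63, adjusted p = 0.0279). TGFBR3 was not called without psoriasis Treg 3 (adjusted p = 0.0517) or psoriasis Teff 2 (0.0505). SKIL was not called without any single library other than psoriasis Treg 2 (adjusted p from 0.0514 to 0.0796).

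The CD8 list fell (median -2.19, adjusted p = 0.00278, and adjusted p = 0.0252 with an estimated correlation; 1 of 5 genes called, 2 when adjusted over the list alone). EOMES was at least 216-fold lower (adjusted p = 0.0238) and GZMK at -4.60 ± 1.75 (adjusted p = 0.331). EOMES was not called without psoriasis Treg 1, 3, 4 or 5 or psoriasis Teff 4 (adjusted p from 0.0505 to 0.0586, and 4.5e-06 to 0.221 over its alternatives). The summed CD8 list was at 5 ± 2.56 CPM in Treg and 30.6 ± 7.63 CPM in Teff (exact permutation p = 0.00794, adjusted p = 0.0635). The summed B and plasma cell list was at 183 ± 74.8 CPM and 29.2 ± 19.1 CPM (exact permutation p = 0.0159, adjusted p = 0.0847). Mast cell markers summed to 1.29 ± 1.12 CPM in Treg and 8.50 ± 4.68 CPM in Teff (exact permutation p = 0.00794, adjusted p = 0.0635). Melanocyte markers summed to 5.23 ± 2.22 and 13.4 ± 5.70 CPM (exact permutation p = 0.0238, adjusted p = 0.0952). Red cell markers summed to 4.12 ± 2.37 and 0.544 ± 0.782 CPM (exact permutation p = 0.0397, adjusted p = 0.127). The mast cell and red cell sums each rest on fewer than 3 tested genes. The list of sort gate genes itself was higher (median 0.49, adjusted p = 2.32e-06, and adjusted p = 0.0277 with an estimated correlation), through IL2RA and CD27 (2 of 7 called, and also 2 when adjusted over the list alone). Immediate early and dissociation stress genes were lower by camera (median -0.64, adjusted p = 0.0133, but adjusted p = 0.476 with an estimated correlation), a call lost without psoriasis Treg 3 (0.0573), psoriasis Teff 1 (0.0833) or 5 (0.181) or the 4 libraries with the fewest genes (0.118). The interferon list was higher by camera (median 0.66, 23 of 29 genes positive, adjusted p = 1.83e-05), which became an adjusted p = 0.0597 with an estimated correlation. In it 3 genes were called (5 higher and 1 lower when adjusted over the list alone), with GBP5 at 3.49 ± 0.56 (adjusted p = 0.00509) and GBP2 at 2.17 ± 0.36 (adjusted p = 0.00584).

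The number called in psoriasis was 66 without psoriasis Treg 3, 73 without psoriasis Teff 2, 74 without psoriasis Teff 4 and 75 without the 4 libraries with the fewest genes. CD27 (3.18 ± 0.64, adjusted p = 0.0239) was not called without psoriasis Treg 3 (0.061) or 4 (0.0526) or psoriasis Teff 1 (0.0796), 2 (0.0801), 4 (0.0977) or 5 (0.062). IKZF2 (3.66 ± 0.77, adjusted p = 0.033) was not called without psoriasis Teff 1 (0.0876), 2 (0.112) or 4 (0.0989) or any 1 psoriasis Treg library (0.0517 to 0.0652). The recirculation and sort gate lists were at an adjusted p = 0.119 and 0.0894 with an estimated correlation when the 4 libraries with the fewest genes were left out. Between healthy and psoriatic skin, 41 of the genes higher in Treg were shared (0.29 by chance from independent lists) and 30 of the lower ones (0.30 by chance). Fold changes over 10042 genes above 5 CPM correlated at r = 0.59 (rho = 0.42) across genes, which are not independent replicates.

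Psoriatic against healthy Tregs is the comparison named in the study's title. The glycolysis list was lower in psoriasis Treg (n = 5 and 5), with a median log2 fold change of -0.81 over 21 genes, 17 of them negative (camera adjusted p = 5.88e-14, and adjusted p = 0.0384 with an estimated correlation; fry adjusted p = 0.0125). The glucose transporter gene SLC2A3 was at 250 ± 69.9 CPM in psoriasis and 796 ± 147 CPM in healthy skin (-1.67 ± 0.29, adjusted p = 0.11). The enolase gene ENO1 was at 3240 ± 555 and 7220 ± 1720 CPM (-1.15 ± 0.24, adjusted p = 0.245) and the phosphoglucose isomerase gene GPI at 482 ± 82.3 and 968 ± 133 CPM (-1.01 ± 0.22, adjusted p = 0.354). The aldolase gene ALDOC was at 67.2 ± 26.9 and 166 ± 39.4 CPM (-1.31 ± 0.32, adjusted p = 0.412). No member was called, and 13 were lower when adjusted over the list alone. Beside this, summed keratinocyte markers were at 19.6 ± 15.4 CPM in psoriasis and 88.7 ± 96.2 CPM in healthy Treg (exact permutation p = 0.0873, adjusted p = 0.381). Psoriatic keratinocyte markers summed to 0.47 ± 0.768 and 62.1 ± 85.5 CPM (exact permutation p = 0.0238, adjusted p = 0.381). Red cell markers, with fewer than 3 tested genes, summed to 4.12 ± 2.37 and 1.05 ± 0.88 CPM (exact permutation p = 0.0476, adjusted p = 0.381). Endothelial markers summed to 3.13 ± 3.04 and 23.5 ± 27.0 CPM (exact permutation p = 0.0952, adjusted p = 0.381). Reads outside genes were at 14.3% ± 3.46 and 12.7% ± 3.59 (exact permutation p = 0.484). Without the 4 libraries with the fewest genes the list was at an adjusted p = 0.056 with an estimated correlation.

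No gene was called between psoriasis and healthy Treg by edgeR, with a smallest adjusted p of 0.102. An unadjusted p under 0.05 was reached by 1460 genes, 560 higher and 900 lower. Of other tests, limma-voom called 0, DESeq2 204 (47 higher, 157 lower), and edgeR 4 lower genes after a filter of at least 5 CPM in 4 libraries. These 4 were the stress kinase gene OXSR1 (48.6 ± 9.08 against 121 ± 26.4 CPM, -1.32 ± 0.21, adjusted p = 0.102), the actin bundling gene PLS3 (0.465 ± 0.555 against 45.3 ± 30 CPM, -6.58 ± 1.13, adjusted p = 0.11), SLC2A3 and ZNF331 (313 ± 116 against 1410 ± 614 CPM, -2.17 ± 0.39, adjusted p = 0.125). They shared an adjusted p = 0.0439 under that filter. IER3, an immediate early gene and NF-kB target, was at least 41.5-fold lower (0 against 1.48 ± 0.998 CPM, adjusted p = 0.182). On the higher side, MEMO1 was at 13.8 ± 5.27 against 2.6 ± 1.1 CPM (2.41 ± 0.49, adjusted p = 0.245). The proteasome assembly gene PSMG3 was at 103 ± 24.6 against 46 ± 11.6 CPM (1.17 ± 0.28, adjusted p = 0.385) and ZNF320 at 1.88 ± 0.50. The transcription factor gene ETV1 was at least 138-fold higher (5.62 ± 5.33 against 0 CPM, adjusted p = 0.444). NPIPB15, 1 of a family of near-identical genes and so uncertain, had 278 counts against 1 (ratio 244, counting interval 43.4 to 9670, adjusted p = 0.385).

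The Treg identity list was lower by camera in psoriasis Treg (median -0.37, 18 of 30 genes negative, adjusted p = 0.0355), a call lost at an adjusted p = 0.305 with an estimated correlation. No member was called, and 1 was lower when adjusted over the list alone, the chemokine receptor gene CCR4 (-1.23 ± 0.30, adjusted p = 0.412). The camera call was also lost without healthy Treg 2 (0.0716), 3 (0.0857) or 4 (0.0745) or psoriasis Treg 1 (0.0925), 4 (0.125) or 5 (0.0561). The Treg genes followed throughout did not pass: FOXP3 0.24 ± 1.02, IL2RA 0.37 ± 0.47, CD27 0.02 ± 0.54, CTLA4 0.55 ± 0.61, IKZF2 -0.72 ± 0.64, LAYN -0.38 ± 0.90 and TNFRSF4 0.25 ± 0.71, with adjusted p from 0.899 to 0.999. ARG2 was at 13.7 ± 4.14 CPM in psoriasis and 61.1 ± 33.3 CPM in healthy Treg (-2.16 ± 1.07, adjusted p = 0.666). CCR6, the chemokine receptor of type 17 cells, was at -1.08 ± 0.55 (adjusted p = 0.682). IL17A had 0 counts in all 10 Treg libraries, IL17F 0 CPM in psoriasis and 0.752 ± 1.68 CPM in healthy Treg (adjusted p = 0.75). IL22 had 1 count against 375 (ratio 428, counting interval 76.3 to 16900, adjusted p = 0.562). Of the healthy Treg libraries, 1 alone held IL17F (3.76 CPM) and 1 alone held IL22 (23.5 CPM). IFNG was at least 21.8-fold lower in psoriasis (0 against 0.78 ± 1.04 CPM, adjusted p = 0.444). IL26 (0.09 ± 1.68), IL10 (0.80 ± 1.04) and IL23R (-0.40 ± 0.95) were within 1 SE of 0.

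Camera called 13 of 36 lists lower and none higher in psoriasis Treg, of which glycolysis and the TGF-beta pathway held with an estimated correlation. The TGF-beta list (median -0.71, 15 of 18 genes negative, adjusted p = 0.00313, and adjusted p = 0.0429 with an estimated correlation) had no called gene and none when adjusted over the list alone. Its members with the smallest p went both ways, TGFBR3 at -1.33 ± 0.42 (adjusted p = 0.488) and the ligand gene TGFB1 at 1.86 ± 0.59 (adjusted p = 0.501). Without the 4 libraries with the fewest genes its adjusted p was 0.294 with an estimated correlation. NF-kB targets (median -0.49, adjusted p = 8.77e-05, but adjusted p = 0.177 with an estimated correlation; 3 of 17 lower when adjusted over the list alone) were lower by camera. They held, besides IER3, the feedback inhibitor gene TNFAIP3 at -1.05 ± 0.34 and TNFAIP2 at -3.20 ± 1.05. Immediate early and dissociation stress genes had a median of -0.67 (adjusted p = 6.35e-06, but adjusted p = 0.239 with an estimated correlation). JUND was at -1.03 ± 0.37 and ZFP36 at -0.85 ± 0.35, with 0 of 23 lower when adjusted over the list alone. Keratinocyte markers (median -4.83, or -4.08 with genes at 0 at their bound) and psoriatic keratinocyte markers (median -7.97, or -6.09) were lower at an adjusted p = 4.35e-05 and 1.78e-06, but adjusted p = 0.305 and 0.23 with an estimated correlation. Adjusted over the list alone, 6 of 14 and 11 of 12 were lower. The desmosome gene DSP had 1 count in psoriasis Treg and 731 in healthy Treg (ratio 833, counting interval 149 to 33000) and DSG3 was at -4.35 ± 1.19. The keratin genes KRT6A and KRT16 were at least 206-fold and at least 75.3-fold lower. None of these 4 passed (adjusted p from 0.245 to 0.484). The endothelial list was lower by camera too (median -2.16 over 4 genes, adjusted p = 0.0355, but adjusted p = 0.305 with an estimated correlation), with none lower when adjusted over the list alone. That call was lost without healthy Treg 2 (0.376) or psoriasis Treg 1 (0.0848), 3 (0.0715) or 4 (0.134).

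**Figure D2:**
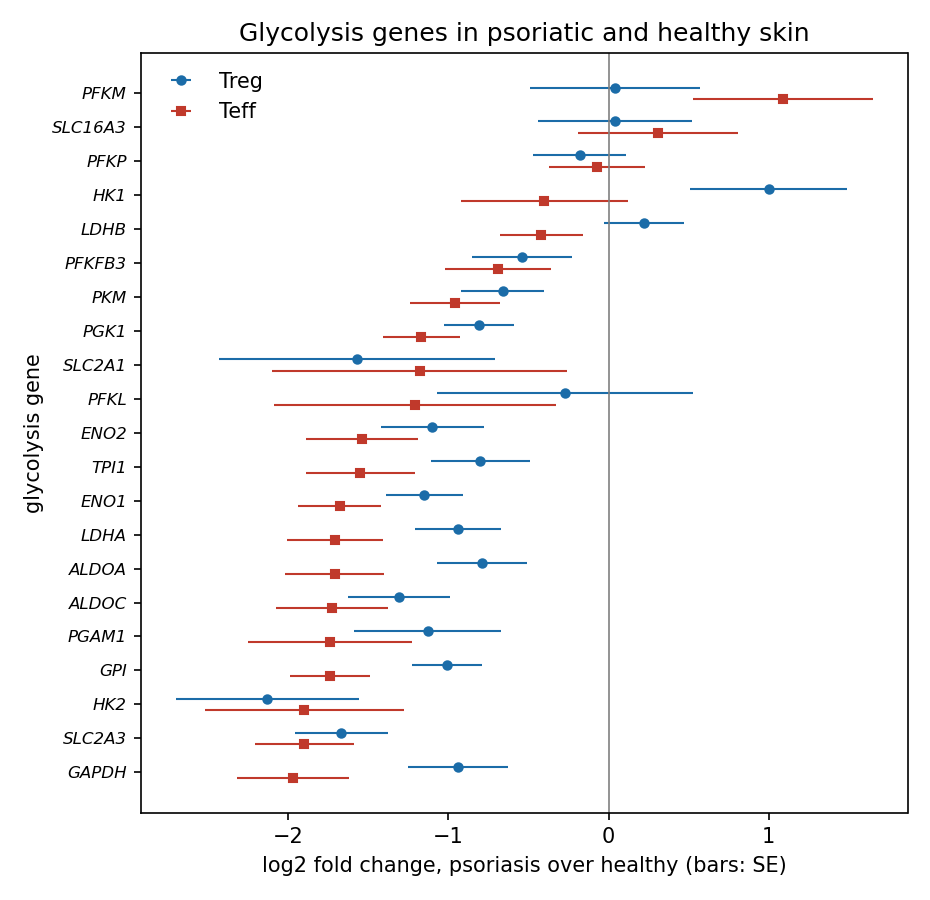
Log2 fold changes, psoriasis against healthy skin, of the 21 tested glycolysis genes in Treg and in Teff; points are edgeR estimates and bars the SE, and the line at 0 is no change. In Treg 17 and in Teff 19 of the 21 genes lay below 0.

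Teffs of psoriatic lesions were then compared with those of healthy skin (n = 4 and 5). Glycolysis genes fell as a group in psoriasis Teff (median -1.54, 19 of 21 negative, camera adjusted p = 1.45e-21, and adjusted p = 0.00638 with an estimated correlation; fry adjusted p = 0.00035). In Teff 2 of them were called and 13 were lower when adjusted over the list alone. Called were GPI (ENSG00000105220), at 348 ± 60.4 CPM in psoriasis and 1160 ± 452 CPM in healthy skin (-1.74 ± 0.25, adjusted p = 0.0138), and ENO1 (ENSG00000074800), at 1590 ± 314 and 5090 ± 1940 CPM (-1.68 ± 0.26, adjusted p = 0.0323). OXSR1 (ENSG00000172939), the stress kinase gene, was the third called gene (45.4 ± 9.11 against 141 ± 17.6 CPM, -1.63 ± 0.23, adjusted p = 0.0138). Close to the threshold were the glucose transporter gene SLC2A3 (552 ± 204 against 2060 ± 700 CPM, -1.90 ± 0.31, adjusted p = 0.0509), and, each at an adjusted p = 0.0725, the lactate dehydrogenase gene LDHA (-1.71 ± 0.30), the glycolytic enzyme genes GAPDH (1500 ± 575 against 5870 ± 3040 CPM, -1.97 ± 0.35) and ALDOA (-1.71 ± 0.31), and CCSER2 (-1.40 ± 0.25).

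Summed over the list, glycolysis genes held 11362 ± 1441 CPM in psoriasis Teff (9947 to 13175) and 32907 ± 11747 CPM in healthy Teff (23311 to 52065), against 16786 ± 2752 and 30527 ± 7145 CPM in Treg. Beside this, keratinocyte markers summed to 22.3 ± 7.78 CPM in psoriasis Teff and 284 ± 300 CPM in healthy Teff (exact permutation p = 0.0714, adjusted p = 0.381). Reads outside genes made up 16.9% ± 1.45 and 10.04% ± 3.33 (exact permutation p = 0.0159). Counts assigned to genes ranged from 13946759 to 14930189 in psoriasis Teff and from 15858422 to 18525504 in healthy Teff libraries (exact permutation p = 0.00794, adjusted p = 0.127). The 50 most abundant genes took 19.2% ± 1.35 and 22.2% ± 2.29 (exact permutation p = 0.0714, adjusted p = 0.381). TMM factors, which scale the CPM, were 1.089 to 1.252 in psoriasis Teff and 0.681 to 1.061 in healthy Teff. This scaling widened the gap of genes lower in psoriasis Teff. The median of genes above 5 CPM was -0.215 with TMM, -0.046 with upper-quartile factors and -0.264 with DESeq2 size factors. The fold changes in Teff stand against that shift.

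**Figure D3:**
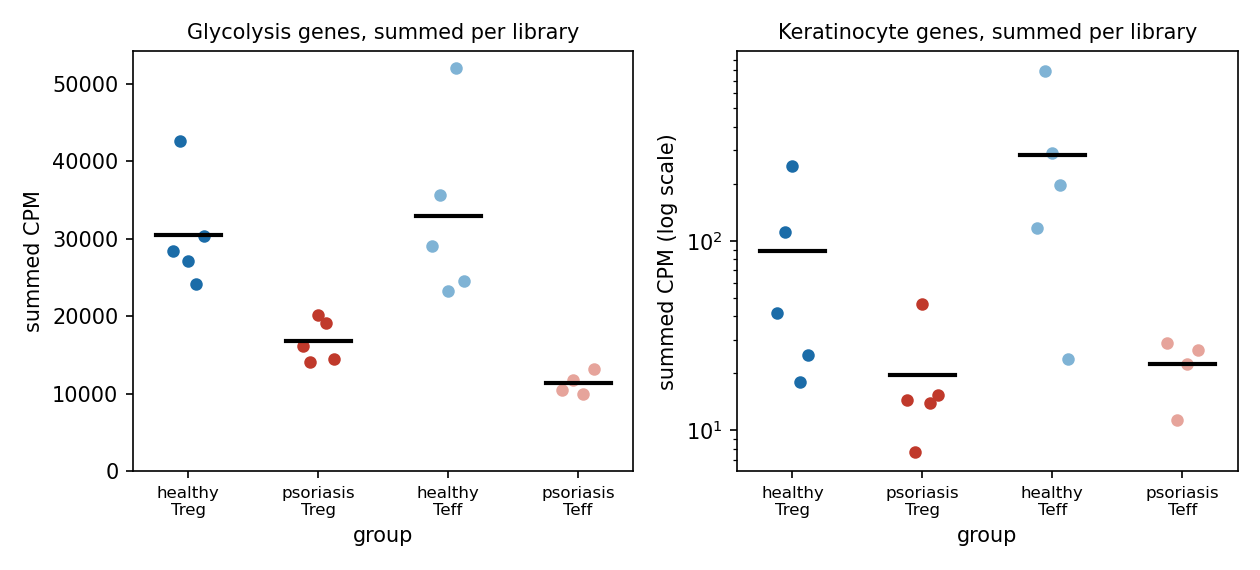
Summed CPM of glycolysis genes (left) and of keratinocyte markers (right, log scale) in each library by group; points are libraries and lines group means. The 5 healthy Teff libraries lie between 23311 and 52065 CPM of glycolysis genes and the 4 psoriasis Teff libraries between 9947 and 13175 CPM.

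All 3 genes called in Teff were lower in psoriasis. In all, 2032 genes had an unadjusted p under 0.05 (822 higher, 1210 lower). No higher gene was called. Those with the smallest p were the noncoding LINC00824 (2.83 ± 0.63, adjusted p = 0.156), the sodium channel subunit gene SCN3B (2.63 ± 0.61), the sphingomyelinase gene SMPD1 (35.1 ± 10.1 against 8.4 ± 1.83 CPM, 2.06 ± 0.49), the melanophilin gene MLPH (3.84 ± 0.92) and DIP2A (1.12 ± 0.27), the last 4 at an adjusted p = 0.174. The number called was 0 without psoriasis Teff 1, 2 or 4, 2 without healthy Teff 2, 6 without psoriasis Teff 5 and 15 without healthy Teff 5. It was 0 in a fit of the 2 groups alone or without the 4 libraries with the fewest genes, and 43 with limma-voom and 386 with DESeq2. Without psoriasis Teff 1, 2 and 4 the adjusted p was 0.0762, 0.0956 and 0.0932 for OXSR1, 0.0813, 0.0956 and 0.0932 for GPI and 0.232, 0.141 and 0.239 for ENO1. The last was also lost without healthy Teff 2 (0.0768). In a fit of the 2 groups alone each was at 0.174, and without the 4 libraries with the fewest genes they were at 0.053, 0.053 and 0.251. Over all alternatives the adjusted p ran from 6.6e-12, 1.15e-09 and 1.83e-07 to 0.759 for each. The 0.759 came from the replicate block, which here joins healthy and psoriasis libraries that share only a number.

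The cytokine genes varied widely between Teff libraries. IL17A was at 13.8 ± 27.7 CPM in psoriasis and 15.1 ± 23.1 CPM in healthy Teff (-0.13 ± 2.47, adjusted p = 0.99) and IL17F at 16.3 ± 32.6 and 22.6 ± 33 CPM (-0.47 ± 2.59). IL22 was at 4.52 ± 9.04 and 42.3 ± 60.6 CPM (-3.22 ± 2.39), IL26 at 5.16 ± 6.71 and 16.1 ± 10.8 CPM (-1.63 ± 1.84) and IFNG at 22 ± 22.5 and 22.3 ± 17.3 CPM (-0.02 ± 1.19). FOXP3 (0.53 ± 1.11), IL2RA (-0.46 ± 0.51), CD27 (-0.27 ± 0.57), CTLA4 (0.47 ± 0.64), IKZF2 (-0.54 ± 0.68), ARG2 (0.66 ± 1.09), LAYN (-0.10 ± 0.99), IL10 (0.12 ± 1.09), IL23R (-0.82 ± 1.02), CCR6 (-0.24 ± 0.58) and TNFRSF4 (-1.60 ± 0.81, adjusted p = 0.484) did not pass.

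In psoriasis Teff camera called 20 of 36 lists lower and none higher, of which glycolysis held with an estimated correlation. Cytosolic ribosomal protein genes had a median of -0.83, with 28 of 28 negative and 0 lower when adjusted over the list alone (adjusted p = 9.42e-11, but adjusted p = 0.19 with an estimated correlation). Among them were RPS3 (1390 ± 268 against 2910 ± 1020 CPM, -1.07 ± 0.34) and RPL4 (-0.80 ± 0.29). NF-kB targets had a median of -0.95, 17 of 17 negative and 0 lower when adjusted over the list alone (adjusted p = 1.48e-05, but adjusted p = 0.074 with an estimated correlation). The adaptor gene TRAF1 was at -1.73 ± 0.59 and the subunit gene REL at -1.27 ± 0.49. Immediate early and dissociation stress genes had a median of -0.74, with 23 of 23 negative and 1 lower when adjusted over the list alone, JUND at -1.46 ± 0.40 (adjusted p = 1.13e-06 for the list, but adjusted p = 0.116 with an estimated correlation). The MHC class II list had a median of -1.17 (adjusted p = 0.000185, but adjusted p = 0.116 with an estimated correlation). CD74 was at 470 ± 320 and 1430 ± 616 CPM (-1.61 ± 0.42) and HLA-DPB1 at -1.08 ± 0.36, and 2 genes lower when adjusted over the list alone. The Treg identity list, lower in Teff than in Treg, had a median of -0.64 (adjusted p = 4.01e-06, but adjusted p = 0.059 with an estimated correlation). In Teff 7 genes were lower when adjusted over the list alone, among them CCR8 (7.95 ± 5.69 against 67.5 ± 40.4 CPM, -3.08 ± 0.70) and TNFRSF1B (-1.26 ± 0.32). Keratinocyte markers (median -6.29, adjusted p = 6.21e-09) and psoriatic keratinocyte markers (median -8.03, or -7.12 with genes at 0 at their bound, adjusted p = 4.01e-06) were lower by camera, but adjusted p = 0.116 and 0.161 with an estimated correlation. Adjusted over the list alone, 13 of 14 and 11 of 12 genes were lower. DSP was at least 698-fold lower (0 against 30.6 ± 38.5 CPM, adjusted p = 0.0902) and SFN had 1 count against 672 (ratio 616, counting interval 110 to 24400). The keratin gene KRT6A had 1 count against 1666 (ratio 1530, counting interval 274 to 60300) and PI3 was at least 58.0-fold lower. Over the 5 comparisons, median, mean and test of a list differed in sign in 28 of 180 results, 0 of them called, such as tissue repair mediators in psoriasis Treg (median 0.33, mean -0.65, lower by test, adjusted p = 0.0768).

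Whether the psoriasis effect differs between Tregs and Teffs was tested as an interaction. The 5 genes with the smallest p on the side where psoriasis had the more positive effect in Treg were PRMT1, an arginine methyltransferase gene (1.92 ± 0.39), the phospholamban gene PLN, ETV1, TMPPE (8.91 ± 2.23) and LINC00402. On the other side they were GOLGA7B (-9.41 ± 2.10), FAM111B (-4.97 ± 1.17), ZNF516, IER3 and SLC6A16 (-6.57 ± 1.69). No size is given for PLN and LINC00402, with 3 counts or fewer in at least 1 group, for ETV1, with 0 counts in healthy Treg, or for ZNF516, IER3 and IFNG, with 0 counts in psoriasis Treg. None passed (edgeR, smallest adjusted p = 0.953), and IFNG, ARG2 (-2.82 ± 1.52), IL2RA (0.84 ± 0.69) and FOXP3 (-0.29 ± 1.51) did not either. An unadjusted p under 0.05 was reached by 911 genes, limma-voom called 0 and DESeq2 73 (41 higher, 32 lower). The median of genes above 5 CPM was 0.169 with TMM and -0.006 with upper-quartile factors. Glycolysis genes differed by a median of 0.44, the fall being the smaller in Treg (camera adjusted p = 0.00336, but adjusted p = 0.501 with an estimated correlation). Ribosomal protein genes differed by 0.46 (adjusted p = 0.000239, but adjusted p = 0.817 with an estimated correlation). In all, 11 lists were called higher and 0 held with an estimated correlation. Fold changes of psoriasis in Treg and Teff correlated at r = 0.40 (rho = 0.27) across 10042 genes, which are not independent replicates.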

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

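Of the comparisons here, that of reads outside genes was added after the data had been seen, and the correlation of keratinocyte markers was stated before its result.

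Single libraries that lay apart from their group were found for 11 of 68 summed levels and other library measures, and for 20 of 130 gene levels. The measure is the gap to the nearest library as a share of the group's whole range. Its rate by chance was not tested for skewed levels or genes seen in 1 library, so these counts show no excess over chance. The libraries lay highest in their group unless stated.

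The summed keratinocyte markers of 1 psoriasis Treg library (46.7 CPM, others 7.69 to 15.4) had a gap of 0.803. Psoriatic keratinocyte markers stood apart in healthy Teff (676 CPM, others up to 108; gap 0.848), healthy Treg (211 CPM, others up to 45.4; gap 0.786) and psoriasis Treg (1.81 CPM, others up to 0.425; gap 0.765). Endothelial markers did so in healthy Teff (105 CPM, others up to 18.1; gap 0.839) and psoriasis Treg (8.46 CPM; gap 0.775). In psoriasis Treg, NK and innate lymphoid markers reached 319 CPM in 1 library (others 24.9 to 59.8; gap 0.881) and neutrophil markers 9.29 CPM (gap 0.755). CD8 T cell markers reached 8.13 CPM in 1 healthy Treg library (gap 0.758), and melanocyte markers 18.3 CPM in healthy Treg (gap 0.800) and 9.09 CPM in psoriasis Treg (gap 0.745).

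Keratinocyte transcripts were concentrated in some healthy libraries, with KRT5 at 46.2, KRT14 at 67.2 and S100A8 at 185 CPM in healthy Teff 2, although the sort for CD45, CD3 and CD4 would remove keratinocytes. Over the 10 healthy libraries the 14 tested markers had a median pairwise Spearman correlation of 0.68, against at most 0.27 in random lists matched on expression. This is consistent with the hypothesis of RNA from keratinocytes in these libraries. Of the 18 listed genes 0 are in another list and 4 were above 1 CPM in both psoriasis groups. Whether such RNA came with whole cells or as free RNA, and any biological explanation, was not tested.

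Among Treg genes, CD27 stood apart in psoriasis Treg (369 CPM, others 115 to 185; gap 0.724), as did CTSC (1160 CPM, others 531 to 700; gap 0.731). IKZF2 did so in healthy Treg (584 CPM, others 215 to 303; gap 0.762) and healthy Teff (69.3 CPM; gap 0.759), and TIGIT in psoriasis Teff (466 CPM, others 313 to 329; gap 0.895). The lowest library of psoriasis Teff stood apart for GLRX (79.9 CPM, others 122 to 127; gap 0.894) and GPI (258 CPM, others 372 to 385; gap 0.898). AOAH (6.56 CPM; gap 0.791), PLAC8 (7.72 CPM; gap 0.800) and IL23R (13.4 CPM; gap 0.782) did so in psoriasis Treg, and CCR6 (99.9 CPM; gap 0.712) and IL10 (15.7 CPM; gap 0.729) in healthy Treg.

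Several genes were detected in 1 library of a group and at 0 in the others, a gap of 1, the whole range. In psoriasis Teff these were IL17A (55.3 CPM), IL17F (65.3 CPM) and IL22 (18.1 CPM). In healthy Treg they were IL17F (3.76 CPM), IL22 (23.5 CPM) and TSPAN2 (0.0661 CPM), and in psoriasis Treg IL22 and TSPAN2 (0.0607 CPM each).

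Reads that overlapped no gene feature, 1 of the counter's 5 lines outside the tested values, made up 16.91% of all entries in psoriasis Teff and 10.04% in healthy Teff (exact permutation p = 0.0159).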

How the results depend on the processing

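The fit without the 4 libraries with the fewest genes and upper-quartile factors for lists were chosen after the data were examined. Of 75 called gene values, 40 held under all their alternatives, 35 were lost under at least 1 and 0 changed sign. Of 341 values not called, 113 were called at least once and 42 changed sign at least once. Size factors of DESeq2 within edgeR and upper-quartile factors kept all 77 list calls, an estimated correlation 15 and fry 37. Without the 4 libraries 57 were kept, and 9 with an estimated correlation as well. Counts of called genes are given for psoriasis against healthy Treg (0), the same in Teff (3), Treg against Teff in healthy skin (196) and in psoriasis (116), and the difference of effects (0). DESeq2 called 204, 386, 765, 696 and 73. A filter of at least 5 CPM in 4 libraries, under which fewer genes were tested, gave 4, 9 and, for Treg against Teff in psoriasis, 192. Limma-voom called 43 in Teff, 443 in healthy skin and 248 in psoriasis. A fit of the 2 groups alone called 0 in Teff and 59 between Treg and Teff in psoriasis. Without the 4 libraries the counts were 0 in Teff, 122 in healthy skin and 75 in psoriasis, with fewer samples. Leaving out 1 library gave 0 to 15 in Teff (0 without psoriasis Teff 1, 2 or 4, 15 without healthy Teff 5), 95 (without healthy Treg 1) to 180 in healthy skin and 66 (without psoriasis Treg 3) to 117 in psoriasis. The ribosomal protein list in psoriasis against healthy Treg (adjusted p = 0.0355) ran from 2.78e-07 without healthy Treg 5 to 0.662 without healthy Treg 2, where its direction reversed. That call did not hold with an estimated correlation. Beyond these constructions, the cause was not tested. Genes at a few counts in a group are limited by depth.

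With the replicate block, 0 genes were called in Teff, 131 in healthy skin (93 shared with the fit without it) and 53 in psoriasis (45 shared), and 71 of 75 list calls were kept. With it OXSR1, GPI and ENO1 in Teff were each at an adjusted p = 0.759, FOXP3 in healthy skin at 0.0618, CCR8 at 0.103 in healthy skin and 0.078 in psoriasis, and IFNG in psoriasis at 0.2. Deviations of same-numbered Treg and Teff libraries correlated at 0.045 to 0.259 in healthy skin, where 4 of 5 Treg and 5 of 5 Teff libraries correlated best with their own number, and at 0.023 to 0.233 in psoriasis (2 and 3 of 4). Between healthy and psoriatic skin they correlated at -0.079 to -0.035 in Treg and -0.082 to -0.064 in Teff, so the libraries share only a number.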

Other observations

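Chosen after the result was seen were the tests with keratinocyte RNA as a covariate and the splits of the libraries, apart from the splits tested with DESeq2, and the hypoxia list was chosen after the glycolysis result was seen.

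The chemokine receptor gene CX3CR1, on the list of cytotoxic effector genes, was higher in Treg. In psoriasis it had 3490 counts in Treg and 2 in Teff (ratio 1420, counting interval 393 to 11700, edgeR adjusted p = 0.00288, and up to 0.0274 over its alternatives). In healthy skin it was at 54 ± 21.3 CPM in Treg and 2.96 ± 4.23 CPM in Teff (4.19 ± 0.98, adjusted p = 0.0474), a call lost without any 1 healthy Treg library or healthy Teff 1, 3 or 5 (adjusted p up to 0.128). The other members lay mostly lower in healthy Treg (12 of 14 genes negative, 1 called higher and 1 lower, 1 higher and 4 lower when adjusted over the list alone; adjusted p = 0.000971, but adjusted p = 0.089 with an estimated correlation). The death ligand gene FASLG had 3 counts in psoriasis Treg and 1645 in Teff (ratio 673, counting interval 230 to 3270, adjusted p = 0.0133), a call lost with limma-voom (0.116, with 4.43e-08 to 0.164 over its alternatives). In healthy skin, HOPX (-3.54 ± 0.61, adjusted p = 0.00689), the residency gene CD69 (478 ± 182 against 1750 ± 799 CPM, -1.87 ± 0.35) and the interleukin 4 receptor gene IL4R (-1.66 ± 0.31, both adjusted p = 0.0134) were lower in Treg.

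The list of B and plasma cell markers had 4 tested genes, none of which was called between Treg and Teff. CD79B, part of the B cell receptor, was at 172 ± 69 CPM in Treg and 27.3 ± 18.7 CPM in Teff of psoriasis (2.65 ± 0.91, edgeR adjusted p = 0.248), and MZB1 was at 3.17 ± 0.83 (adjusted p = 0.104). The B cell surface gene MS4A1 went the other way, with 2 counts in healthy Treg and 787 in healthy Teff (ratio 388, counting interval 107 to 3210, adjusted p = 0.0869). By camera the list was higher in psoriasis Treg (3 of 4 genes positive, adjusted p = 0.0146, but adjusted p = 0.0597 with an estimated correlation), a call lost without psoriasis Teff 1 (0.0833) or 5 (0.181). It was not called in healthy skin (median 1.22, mean -0.80, adjusted p = 0.19).

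Glycolysis genes were lower in psoriasis in both populations (medians -0.81 in Treg and -1.54 in Teff). With the share of reads outside genes in the fit the medians were -0.68 and -0.87 (adjusted p = 0.00294 and 0.00347 with an estimated correlation). In Treg this argues against that share as the whole cause. In Teff the share did not overlap between the groups (15.54% to 18.94% against 4.7% to 13.47%), so the fit cannot fully separate it from diagnosis. Random lists matched on expression fell too, with medians centred on -0.23 in Treg and -0.46 in Teff. Of 10000 such lists 0.00% had a median as low as glycolysis in either, so the list fell further than other genes of like expression. The random genes were drawn independently, without the correlation within a pathway, and the glycolysis list was singled out for its p. This percentage therefore does not exclude a fall by chance. With keratinocyte RNA in the fit the medians were -0.67 (16 genes lower, from 17) and -0.91. With an estimated correlation the Teff call held (adjusted p = 0.0225). The Treg call ended (adjusted p = 0.206, but 4.39e-07 at the preset correlation). The fall of the summed keratinocyte markers was 0.951% and 2.05% of that of the glycolysis sum. Markers are only part of a keratinocyte's RNA, so this share alone does not measure what keratinocytes contributed. Healthy Treg 4 and 5 had keratinocyte sums of 17.92 and 25.08 CPM (psoriasis Treg 7.69 to 46.68). Their glycolysis sums were 24114 and 30397 CPM (psoriasis Treg up to 20210), but DSP was at 9.06 and 12.96 CPM (up to 0.06). Healthy Teff 5 had 23.92 CPM of keratinocyte markers (psoriasis Teff 11.39 to 28.83) and 24518 of glycolysis genes (up to 13175). Higher glycolysis sums were thus also seen where keratinocyte sums lay within the psoriasis range. A candidate explanation is a weaker hypoxia response: 20 tested hypoxia-induced genes without glycolytic enzymes had medians of -1.14 in Treg and -1.11 in Teff (adjusted p = 0.0156 and 0.0404 with an estimated correlation, 19 lower in each), with P4HA1 at -1.48 ± 0.47 and -2.22 ± 0.53. Camera called 13 lists in Treg and 20 in Teff, all lower, so 1 more lower list says little by itself. The hypoxia list was not put through the covariate fits, random lists or splits. Keratinocyte RNA or a factor that moves with it stays open, above all in Treg. The lower counts per library in psoriasis Teff were not tested as a cause. Any batch or handling that differed between healthy and psoriatic skin cannot be told apart from diagnosis.

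Of 100 splits of the libraries, 1, the real one, gave the glycolysis list as small a camera p (1.63e-15 against 2.18e-08 in the next for Treg, 4.02e-23 against 2.58e-17 for Teff), but this list was singled out for its p. Counting any of the lists, 7 of 100 splits gave as small a p in Treg (lowest other 6.85e-25), so chance could not be excluded there. In Teff only the real split did among the 100 drawn of 126 possible (lowest other 1.49e-21). For the genes called in Teff the margin was small (3, highest other split 2), so chance could not be firmly excluded. Those calls fell to 0 without psoriasis Teff 1, 2 or 4. For that comparison the simulation gave 6 false calls. They came beside 18, 39 and 49 changed genes recovered at true folds of 4, 16 and 64. The simulation therefore does not show how many of the 3 real calls are false. Chance could be excluded for the genes called between Treg and Teff in healthy skin (196, highest other 1) and psoriasis (116, highest other 3). For any list in healthy skin, the smallest camera p was 3.15e-23 in the real split, for Treg identity. Another split reached 2.21e-36, for ribosomal protein genes, so a list p this small does not by itself exclude chance there. In psoriasis the real split gave 4.78e-35 and the lowest other 3.74e-23. With 0 genes called for psoriasis against healthy Treg (highest other 2) and for the difference of effects (highest other 5), all 100 splits give as many by construction, so their number tests nothing there. The number of lists called was 13 in Treg (highest other split 13), 20 in Teff (23) and 18 in healthy skin (18). It was 15 in psoriasis (15) and 11 for the difference (18). The other splits had medians of 3, 7, 5, 4 and 4 lists in that order. At least as many lists were called in 2, 5, 2, 2 and 20 of 100 splits, the real one included, so each count was matched.

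DESeq2 called 204 genes between psoriasis and healthy Treg where edgeR called 0. Of 40 splits of these libraries 2 gave DESeq2 as many calls, the highest other 270 and the median of the others 80, so chance could not be excluded. In simulated counts for this comparison, drawn with edgeR's own dispersions, DESeq2 made 64 false calls and edgeR 1. At true folds of 4, 16 and 64 DESeq2 recovered 29, 55 and 59 changed genes there and edgeR 15, 44 and 55.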
